A study of Mus musculus with 18 samples.

How the data were processed

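RNA from mouse hippocampus and cerebellum was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample. The 18 arrays fall into 6 groups of 3: transgenic and wild-type hippocampus at 10 weeks of age, transgenic and wild-type hippocampus at 20 weeks, and transgenic and wild-type cerebellum at 10 weeks. Per the labels' protocols, each array was hybridised with equal amounts of RNA pooled from 3 to 4 animals. An array therefore stands for a pool, and the p-value of a gene measures only the spread between pools. The labels give the 10-week animals as males and the 20-week animals as females, so that age and sex changed together in the hippocampus. The mice were of a mixed DBA and C57BL/6J background, and the controls were wild-type littermates, per the series record.

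Tissue was placed in a stabilising solution after dissection, and total RNA was extracted with TRI reagent, treated with DNase, cleaned on columns and labelled with biotin, per the labels' protocols. The submitters' processing notes name RMA and the oligo package. RMA corrects the background of each array, forces the arrays of a run to 1 distribution and summarises the probes of each probe set. The deposited values are log2 expression per probe set, as the authors made them. Versions of both tools are not given in the sources used here. The value table has 35556 probe sets and 1 missing cell, and no column without a sample. The number of arrays limits the precision.

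Within each set of 6 arrays (1 tissue at 1 age), 76 to 150 exact values recurred between any pair of arrays, and between sets at most 2 did. The 3 sets were therefore taken as separate RMA runs. Levels are compared only within a set. The tests of age and of tissue in wild-type mice, fixed before the data were examined, were not run for this reason, and levels of sex-linked and tissue-marker genes are given only as a description of the sets. Differences between genotype effects were kept, because each effect is formed within 1 set.

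Gene names came from the platform's annotation, which may be old. Of the probe sets, 23410 are listed there with genes, 21789 with exactly 1 symbol, 1621 with several symbols, and 12146 are not listed. Symbols were updated by gene number through a RefSeq table of the GRCm38.p6 assembly, which matched 21698 of the probe sets with 1 symbol. That table served only for names and for which genes neighbour each other, and no coordinates are given, because no source used here names the assembly behind the array. For the 999 genes with over 1 probe set, the probe set with the highest mean over all arrays was used, which left 19938 genes. No filter on dim genes was applied in the main test.

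Genes were tested with limma 3.58.1 in R 4.3.3. A single linear model with a mean for each of the 6 groups was fitted to the deposited log2 values, with 12 residual degrees of freedom and with moderated variances (eBayes, without trend). The contrasts were transgenic minus wild type in each set, the 20-week minus the 10-week hippocampus effect, and the cerebellum minus the hippocampus effect at 10 weeks. A gene was called where the Benjamini-Hochberg adjusted p over all 19938 genes was below 0.05. Every adjusted p given for a gene comes from this limma test and is two-sided. Fold changes are back-transformed from log2 differences, SE is the moderated standard error, and SD is the spread of 3 arrays.

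Before the data were examined, 35 gene lists were fixed from textbook knowledge, covering cell types of the brain, receptors and channels, activity-dependent genes, metabolic and stress pathways, and genes that differ between the parental strains or sexes. A list with fewer than 5 measured members was not tested, which left 34 lists per comparison. Lists were tested with camera at a preset inter-gene correlation of 0.01, which compares the genes of a list with all other genes. At that setting the members of a list count as nearly independent. Its p-values can therefore overstate the evidence where members move together. Adjustment was over the 34 lists. Each list was tested again with a correlation estimated from its members, and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Of the blood cell list only 6 of 12 members were measured, and that list was left out of checks.

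Single genes are named by a rule fixed before the data were examined. For each genotype effect it takes the 10 largest rises and the 10 largest falls among called genes whose 3 transgenic and 3 wild-type values do not overlap, filled up to 5 per direction by smallest p. For each list described it takes up to 4 members of smallest p, and for each difference of effects up to 5 genes of smallest p per direction. Htt, Prnp, Xist, Eif2s3y, Ddx3y, Kdm5d and Uty are always included, and predicted genes are counted without being named. Ddx3y had no measured probe set with 1 symbol. Genes outside this rule are said to have been chosen after their values were seen.

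The steps were tested on simulated data, made from the real mean of each gene in each set and its residual spread. With 100 genes changed by each size in each set, a change of 0.5 on the log2 scale was called in 76% of the genes in 10-week hippocampus, 73% in 20-week hippocampus and 69% in cerebellum. A change of 1 was called in 99%, 99% and 98%. Of all calls, 3.85%, 3.91% and 4.57% were false. A shifted gene list ranked 1 of 34, and 0 other lists were called, not counting lists that share a member with it. The simulated noise was independent between genes and had the same spread on all arrays. The simulation therefore does not show how the steps fare with correlated genes or with an array that stands apart.

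Replicate numbers are shared between transgenic and wild-type groups. The pairing was checked by correlating, across genes, the deviations of same-numbered arrays from their group means. In cerebellum the correlations were 0.11, 0.28 and 0.18 for numbers 1, 2 and 3, so the numbers were taken as pairing the samples there. In 10-week hippocampus they were −0.56, 0.45 and 0.12, so values of this size do not by themselves show a pairing. The pairing in cerebellum comes only from the values, and no label explains what the numbers stand for. The main model was fixed without a block. Results with it are given where it takes away the cerebellum call of a gene named here. Tallies of list members come from the main model, and genes called only with the block are not listed.

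The alternatives tried were the fit with only the arrays compared, the replicate number as a block, quantile normalisation across the arrays of each tissue, median centring of each array, a filter on dim genes at percentile 30, every probe set tested on its own, the mean of a gene's probe sets, a trended and robust variance, array weights, thresholds of 0.01 and 0.1 on the adjusted p, fold thresholds of 1.2 and 1.5, and leaving out each array in turn. Quantile normalisation within each set, the rescaled tests of gene lists, median centring for the named genes, and fits without transgenic array 1 of 20-week hippocampus, which stood apart, were added after the data had been seen.

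Correlations of effects between comparisons are across genes. Fisher's exact test, two-sided, was fixed beforehand for the overlap of called genes, but its p-values are not given, because the lists share the spread of each gene and are not independent. Gene families named by a shared symbol stem were tested with Fisher's exact test, one-sided. That test counts the genes of a family as independent and does not measure the spread between pools. Arrays of each set were also split anew into 3 against 3 in all 10 ways, of which the smallest possible share is 0.1.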

Results

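Gene expression was measured in N171-HD82Q mice, which carry an N-terminal fragment of human huntingtin with an expanded glutamine repeat under the mouse prion protein promoter and serve as a model of Huntington's disease, and in their wild-type littermates. The data comprise 3 arrays per genotype from hippocampus at 10 weeks, hippocampus at 20 weeks and cerebellum at 10 weeks, 18 arrays in all, with RNA of several animals pooled on each array. The 10-week pools were of males and the 20-week pools of females. Values are log2 expression, and the 3 sets were taken as normalised separately. Array 1 of transgenic hippocampus at 20 weeks had a mean correlation of 0.973 with the other arrays of its group over all probe sets, and leaving it aside the lowest correlation within a group was 0.98997.

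Sex-linked genes matched the labels in every group. Xist, transcribed from the inactive X chromosome, lay at a mean of 4.52 (SD 0.0455, n = 3) in wild-type hippocampus at 10 weeks and at 11.05 (SD 0.0893, n = 3) at 20 weeks. The Y-linked gene Eif2s3y lay at 7.97 and 3.77 in the same groups, and at 10.45 in wild-type cerebellum. Kdm5d and Uty, which are Y-linked as well, lay at 7.48 and 7.61 at 10 weeks and at 4.57 and 3.92 at 20 weeks. Gabra6, a GABA receptor subunit of cerebellar granule cells, lay at 4.42 (SD 0.0774) in wild-type hippocampus and at 13.03 (SD 0.0572) in wild-type cerebellum at 10 weeks. The hippocampal markers Prox1 (8.65 and 9.55) and Wfs1 (9.63 and 9.61) were singled out after their values were seen. The medians of the same arrays lay between 6.21 and 6.34 in hippocampus and between 7.64 and 7.68 in cerebellum, so the levels of Prox1 and Wfs1 do not show which tissue had more. Levels from different sets are given without a test.

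Prnp, the gene whose promoter drives the transgene, was higher in every transgenic array than in every wild-type array of its set. It rose from 10.64 (SD 0.072) to 11.35 (SD 0.0736) in hippocampus at 10 weeks, from 11.38 (SD 0.047) to 12.1 (SD 0.0779) at 20 weeks and from 11.68 (SD 0.0863) to 12.74 (SD 0.0324) in cerebellum, with n = 3 per group. The corresponding changes were 1.64-fold, 1.66-fold and 2.1-fold. The Htt probe set differed by 0.0081, 0.055 and 0.037 on the log2 scale (adjusted p = 1, 0.676 and 0.796) and was not called. It was designed for the mouse gene, and whether it detects the human fragment is not given in the sources used here. Whether the Prnp probe set also detects transcripts of the transgene is not given either. The rise of Prnp need therefore not be one of the mouse gene's own transcript.

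**Figure D1:**
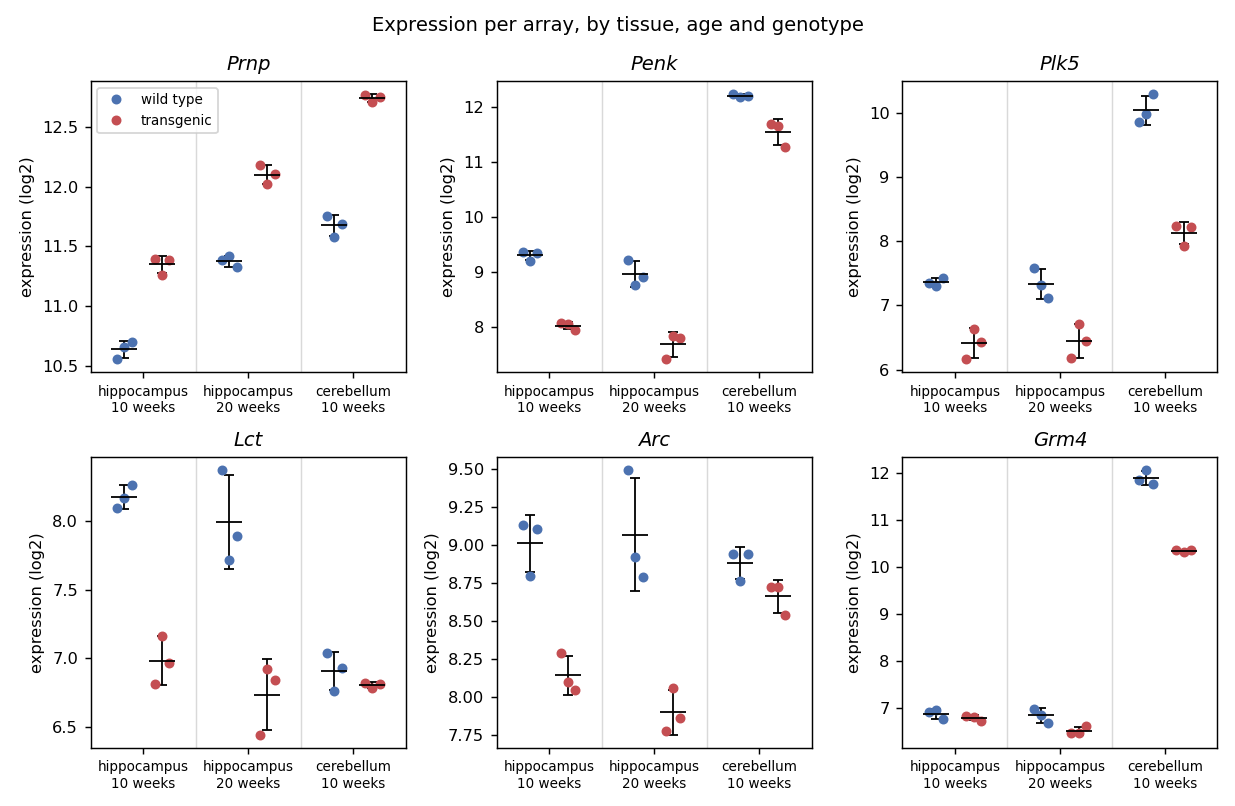
Expression of 6 genes on each array (log2, vertical axis) in the 3 sets (horizontal axis), with wild-type arrays in blue and transgenic arrays in red. Points are the 3 arrays of a group, black bars are the mean ± SD, and levels are comparable only within a set.

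The first comparison asked which transcripts differed in the transgenic hippocampus at 10 weeks. Most of the called genes were lower in the transgenic animals. Penk, which encodes the precursor of the enkephalins, fell by 1.28 on the log2 scale (SE 0.125, 2.43-fold, adjusted p = 5.84e-05), from 9.3 (SD 0.0845) to 8.02 (SD 0.0709), with n = 3 per group. Ptgs2, the inducible cyclooxygenase, and Lct each fell by 1.19 (SE 0.149 and 0.141), and Itpka, a neuronal kinase that phosphorylates inositol trisphosphate and binds actin, fell by 1.05 (SE 0.164). Tafa1, Lrrc10b, Strip2, the polo-like kinase gene Plk5, the epidermal lipoxygenase gene Alox12b and Rasl10a completed the 10 largest falls, between −1.05 and −0.91. The largest rises were those of Rgs13, a regulator of G-protein signalling, by 0.81 (SE 0.137, 1.75-fold, adjusted p = 0.00419), and of Prnp. Wild-type Rgs13 lay at 4.77, below the lower quartiles of its arrays (4.86 to 4.99), so its fold change starts from a low level. Olfm2, the neurotensin receptor gene Ntsr1 and the CaMKII inhibitor gene Camk2n2 rose by 0.61, 0.57 and 0.49.

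Among 19938 genes, limma called 20 as higher and 151 as lower in transgenic hippocampus at 10 weeks. A fold change of at least 1.5 was reached by 58 of them, 4 higher and 54 lower. In 2984 genes (15%) the values of the 3 transgenic and 3 wild-type arrays did not overlap, and these included every called gene. By chance 1 gene would part in this way with a probability of 10%. Genes that move together can part together, so the share of genes is not a test. With the hippocampus arrays forced to 1 distribution the split moved to 120 higher and 375 lower. Leaving out 1 array lowered the count to 113 (wild-type array 2), 110 (wild-type array 3), 110 (transgenic array 1), 101 (transgenic array 2) or 82 (transgenic array 3).

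Further rises were seen in the voltage-gated sodium channel genes Scn7a (0.67) and Scn9a (0.56), the noncoding RNA Dubr (0.54), the endothelin-converting enzyme gene Ece2 (0.51) and the amino acid transporter gene Slc6a15 (0.50). Each of these lost its call without certain single arrays. Scn7a lost it without wild-type array 2 or 3 or transgenic array 1 or 2 (adjusted p up to 0.105), Scn9a without any array but wild-type array 2 (up to 0.111), and Slc6a15 without any but wild-type array 3 (up to 0.0963). Dubr and Ece2 lost it without any 1 of the 6 arrays (up to 0.267 and 0.158).

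Markers of dentate granule neurons fell as a group in 10-week hippocampus. All 16 measured members had negative log2 changes, with a median of −0.63, and 11 of them fell while 5 did not pass the test; 14 fell when adjusted over the list alone. The members of smallest p were Lct, the cation channel gene Trpc6 (−0.87, SE 0.109), the matrix protein gene Npnt (−0.62) and the ciliogenic transcription factor gene Rfx3 (−0.63). The list passed camera (adjusted p = 5.31e-40), also with an estimated correlation (adjusted p = 0.00634). Markers of pyramidal neurons of the hippocampal CA fields fell too, with a median of −0.33 over 17 members, all of them negative. Of these, 4 fell (13 when adjusted over the list alone): the endoplasmic reticulum membrane protein gene Wfs1 (−0.87), the transcription factor gene Neurod6 (−0.80), Spink8 (−0.80) and Bok (−0.60), and 13 did not pass. Spink8 lost its call without wild-type array 1 or 3 or transgenic array 2 or 3 (adjusted p up to 0.0918), and Bok without any array but wild-type array 2 (up to 0.154). That list held with an estimated correlation (adjusted p = 0.0298), and these were the only 2 of the 16 called lists that did. Over the 6 alternatives the adjusted p reached from 1.82e-39 to 0.00634 for the first list and from 3.04e-24 to 0.0298 for the second.

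Immediate early genes, which neurons transcribe within minutes of activity, had a median change of −0.24 in 10-week hippocampus, with 26 of 29 members negative. Of these, 5 fell and 24 did not pass; adjusted over the list alone, 12 fell. The 5 were Ptgs2 (−1.19), Arc (−0.87, SE 0.141), a synaptic scaffold regulator, Npas4 (−0.54), Jun (−0.41) and Homer1 (−0.40). Npas4, chosen after its values were seen, lost the call without any array but wild-type array 3 (adjusted p up to 0.221), Jun without any but transgenic array 1 (up to 0.212) and Homer1 without transgenic array 3 (0.0533). The list passed camera and was lost with an estimated correlation (adjusted p = 0.0655). Over its 6 alternatives the adjusted p ran from 5.34e-21 to that value.

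Signalling and channel lists were lower as well at 10 weeks. Of 37 calcium signalling genes, 5 fell, 1 rose and 31 did not pass, with a median of −0.14 (14 lower and 2 higher adjusted over the list alone; adjusted p = 0.101 with an estimated correlation). Itpka fell by 1.05 and Stim2, a calcium sensor of the endoplasmic reticulum, by 0.36, a call lost without transgenic array 2 (adjusted p = 0.0516). The protein kinase C genes Prkca (−0.41) and Prkcb (−0.33) lost their calls without wild-type array 2 or 3 or transgenic array 2 or 3 (up to 0.131 and 0.134). Ppp3ca (−0.29) and Camk2d, which rose by 0.40, were chosen after their values were seen; the first lost its call without any array but wild-type array 1 (up to 0.222) and the second without any but transgenic array 2 (up to 0.152). Of 34 potassium channel genes, 4 fell and 30 did not pass, with a median of −0.13 (10 lower and 1 higher adjusted over the list alone; adjusted p = 0.167 with an estimated correlation). They were Kcnh3 (−0.71, SE 0.109), Kcnk4 (−0.70, SE 0.117), Kcnh7 (−0.53) and Kcnq3 (−0.33). Kcnh7 lost the call without wild-type array 1 or 3 or transgenic array 2 or 3 (up to 0.179), and Kcnq3 without any 1 array (up to 0.251).

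Receptor and peptide lists followed in the same comparison. In the glutamate receptor list 1 of 21 members fell, the NMDA receptor subunit gene Grin2a (−0.68, SE 0.0961), with a list median of −0.09 (3 lower adjusted over the list alone; adjusted p = 0.268 with an estimated correlation). In the GABA receptor list 1 of 12 fell, the extrasynaptic subunit gene Gabrd (−0.44), with a median of −0.10 (3 lower adjusted over the list alone; adjusted p = 0.084 with an estimated correlation). Penk and the granin gene Chgb (−0.68, SE 0.0787) were the 2 that fell of 25 neuropeptide and granin genes (2 lower and 1 higher adjusted over the list alone; adjusted p = 0.245 with an estimated correlation). Chgb, Grin2a and the calcium buffer gene Calb1 (−0.48) were the 3 that fell of 25 neuronal genes controlled by the repressor REST (3 over the list alone; adjusted p = 0.255 with an estimated correlation). Penk and Rasd2, a small GTPase gene (−0.67), fell out of 20 genes of striatal projection neurons that are often lower in Huntington's disease models (2 over the list alone; adjusted p = 0.531 with an estimated correlation). Rasd2 lost its call without wild-type array 3 or transgenic array 3 (adjusted p up to 0.0698). In the circadian clock list only Bhlhe40 (−0.69) fell of 16 (4 over the list alone; adjusted p = 0.209 with an estimated correlation), a call lost without wild-type array 3 or transgenic array 2 or 3 (up to 0.0599).

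Astrocyte, microglial and oligodendrocyte markers were not called as lists at 10 weeks. Medians were 0.0087 for astrocytes (adjusted p = 0.694), 0.0073 for microglia and macrophages (0.876) and −0.0097 for oligodendrocytes (0.238), and 0 members of these lists were called; adjusted over each list alone, 0 members passed as well. Choroid plexus markers had a median of −0.13 with 0 of 17 called, and the list's call (camera adjusted p = 0.0164) was lost under the other scaling and with an estimated correlation (adjusted p = 0.0858 and 0.706, in a range of 0.0105 to 0.756 over its alternatives). The choroid plexus gene Ttr lay at 8.77, 11.49 and 12.45 on wild-type arrays 1, 2 and 3. On the transgenic arrays it lay between 10.97 and 11.93. The wild-type arrays thus lay far apart, and changes of this list, here or between sets, need not be genotype effects. GABAergic interneuron markers passed camera as lower (median −0.026, 14 of 19 negative, 0 called, 2 lower over the list alone; adjusted p = 0.00928, and 0.531 with an estimated correlation). So did chaperones (−0.081, 0 of 26 called; 0.00307 and 0.531), glucocorticoid response genes (−0.021, 1 of 19 lower; 0.0143 and 0.531) and cholesterol synthesis genes (−0.064, 0 of 20 called; 0.0224 and 0.706). The glucocorticoid-induced gene Fkbp5 (−0.42) was the 1 that fell, a call lost without any array but wild-type array 2 (adjusted p up to 0.256). Of the 34 lists, 16 were called and all were lower. The estimated correlation gave the highest of 6 adjusted p-values for 14 of the 16 lists. For 4 lists, none of them called, the median, the mean and the test differed in sign.

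**Figure D2:**
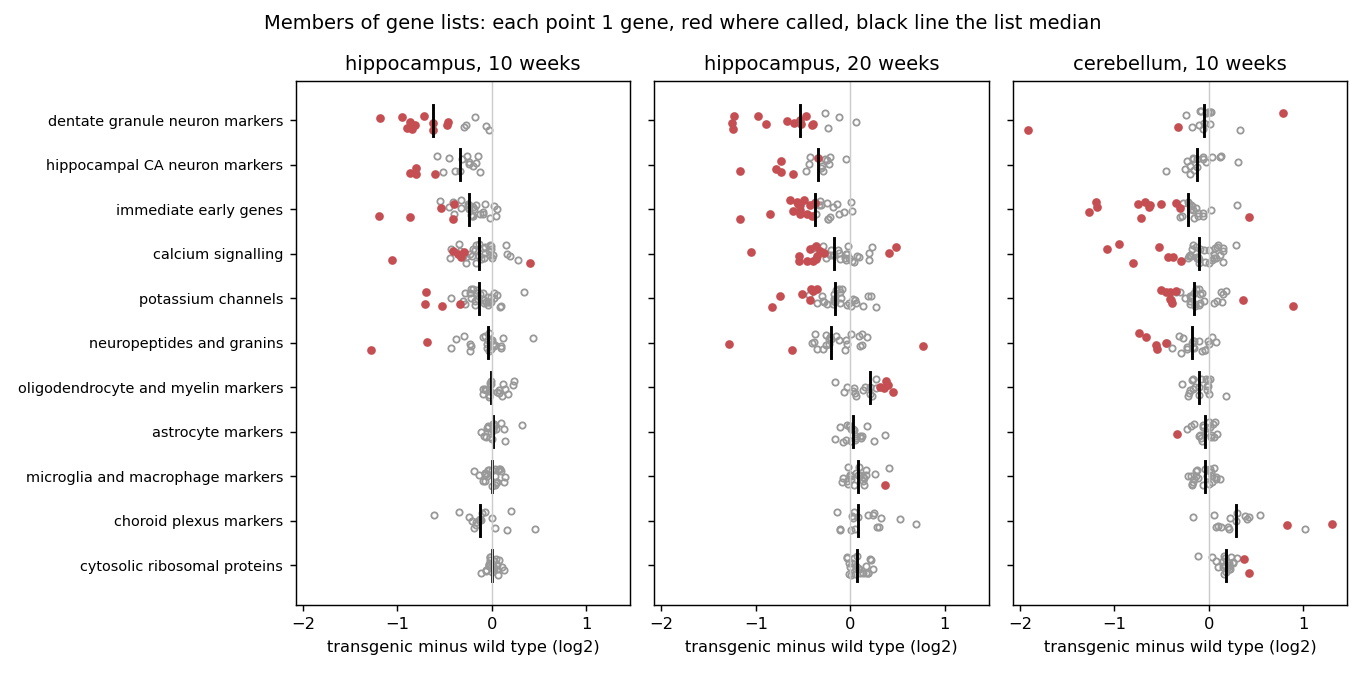
Log2 changes (transgenic minus wild type, horizontal axis) of the members of 11 gene lists (vertical axis) in the 3 genotype comparisons. Each point is 1 gene, red where called, and the black line is the list median, which for dentate granule neuron markers lay at −0.63, −0.53 and −0.05.

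The second comparison asked the same of the hippocampus at 20 weeks. The largest falls were those of Lrrc10b, by 1.42 (SE 0.171, 2.67-fold, adjusted p = 0.000139), and again Penk, by 1.28 (SE 0.125, 2.43-fold, adjusted p = 2.09e-05), with n = 3 per group. Lct, the complement-like synaptic protein gene C1ql2, the desmosomal gene Dsp, Wfs1, Arc and Ddn, which encodes a dendritic postsynaptic protein, fell by 1.25, 1.24, 1.23, 1.17, 1.17 and 1.14. Scn7a rose by 1.095 (SE 0.134, 2.14-fold, adjusted p = 0.000149), followed by the corepressor gene Skor1 (0.99), Rgs13 (0.97), the contactin gene Cntn6 (0.87) and Nts (0.77), the precursor gene of neurotensin. Scn9a (0.74), Prnp (0.73), Bex4 (0.73), Spag6 (0.72) and Capsl (0.72) made up the rest of the 10 largest rises. All of these genes kept their calls when any 1 array was left out. Wild-type Rgs13 and Bex4 lay at 4.79 and 4.72, below the lower quartiles of their arrays (4.86 to 4.89). Wild-type Scn7a lay at 4.98, little above them. Of the 10 largest rises all but that of Prnp started below the lowest wild-type array median (6.01).

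At 20 weeks limma called 1119 genes, 520 higher and 599 lower, and 131 of them changed by at least 1.5-fold, 37 higher and 94 lower. The groups did not overlap in 4064 genes (20.4%, where 10% is the chance for 1 gene), 1058 of them called. Median centring of the arrays turned the split to 751 higher and 435 lower. Transgenic array 1 stood apart from the others, and without it limma called 6445 genes (4182 higher, 2263 lower). Leaving out wild-type array 1 gave 259, wild-type array 2 gave 495, transgenic array 2 gave 581 and transgenic array 3 gave 413. With the spread estimated from the 6 arrays of this age alone, limma called 0 genes (2835 at an unadjusted p below 0.05).

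Dentate granule neuron markers fell in 12 of 16 members at 20 weeks, with a median of −0.53 (14 adjusted over the list alone; 4 did not pass). C1ql2, Dsp, Lct and Stxbp6 (−0.98, SE 0.12) had the smallest p-values. CA neuron markers fell in 7 of 17, with a median of −0.34 (15 over the list alone), and Wfs1, the apoptosis regulator gene Bok (−0.79), Lefty1 (−0.74) and Neurod6 (−0.73) led. Among immediate early genes 14 of 29 fell, with a median of −0.38 (19 over the list alone), including Arc (−1.17), the phosphatase gene Dusp5 (−0.64), and the AP-1 genes Jun (−0.56) and Fosl2 (−0.53). With an estimated correlation the adjusted p-values of these 3 lists were 0.166, 0.221 and 0.221, the highest of 7 alternatives. Without transgenic array 1, which stood apart, their medians were −0.43, −0.22 and −0.29, and all 3 lists still passed camera (adjusted p = 1.4e-08, 1.21e-05 and 1.26e-07).

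Some channel and receptor genes fell at 20 weeks and others rose. Of 34 potassium channel genes 7 fell, with a median of −0.17, among them Kcnk4 (−0.83, SE 0.117), Kcnh3 (−0.75, SE 0.109) and Kcnj9 (−0.42) (14 lower and 1 higher adjusted over the list alone; adjusted p = 0.6 with an estimated correlation). Of 37 calcium signalling genes 11 fell and 2 rose, with a median of −0.17 (16 lower and 4 higher over the list alone; adjusted p = 0.6 with an estimated correlation). Itpka fell by 1.05, Prkcb by 0.39 and Stim2 by 0.37, while Camk2d rose by 0.48 and the T-type channel gene Cacna1g by 0.41. In the neuropeptide and granin list Penk and Chgb (−0.62) fell and Nts rose, of 25, with a median of −0.20 (8 lower and 1 higher over the list alone; adjusted p = 0.6 with an estimated correlation). Among 21 glutamate receptor genes 4 fell, with a median of −0.08: Grin2a (−0.79, SE 0.0961), the presynaptic receptor gene Grm2 (−0.69), Gria1 (−0.34) and Grm4 (−0.32) (4 over the list alone; adjusted p = 0.724 with an estimated correlation). Gria1 lost its call without wild-type array 1 or 2 (adjusted p up to 0.0735), and Grm4 without wild-type array 1 or 2 or transgenic array 2 or 3 (up to 0.224). The GABA receptor list was not called (adjusted p = 0.131), and 2 of its 12 members fell, Gabra5 (−0.65) and Gabrd (−0.45) (3 lower and 1 higher over the list alone). Gabra5 lost its call without wild-type array 1 (adjusted p = 0.119). Of 20 striatal projection neuron genes 4 fell and 1 rose, with a median of −0.15 (5 and 1 over the list alone; adjusted p = 0.724 with an estimated correlation). Without transgenic array 1 the glutamate receptor and striatal lists were no longer called (adjusted p = 0.184 and 0.37).

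Oligodendrocyte and myelin markers rose as a group at 20 weeks, with a median of 0.20 over 19 members, of which 5 rose and 14 did not pass (8 over the list alone; adjusted p = 0.724 with an estimated correlation). The myelin genes Aspa (0.45), Opalin (0.40, chosen after its values were seen), Mog (0.36) and Cnp (0.32) each lost the call without any array but transgenic array 1 (adjusted p up to 0.163, 0.217, 0.192 and 0.108), and Tspan2 (0.38) without wild-type array 1 or transgenic array 2 or 3 (up to 0.147). Without transgenic array 1 the list median was 0.30. Cytosolic ribosomal protein genes had a median of 0.068 with 0 of 23 called, and the list's call was lost with an estimated correlation (adjusted p = 0.724), without transgenic array 1 (0.0609) and under quantile normalisation (0.0581). GABAergic interneuron markers (median −0.17, 0 of 19 called, 3 lower over the list alone) and meningeal markers (median −0.16, 1 of 16 called, 5 over the list alone) were lower with estimated-correlation adjusted p-values of 0.74 and 0.679. Both lost their calls without transgenic array 1 (adjusted p = 0.461 and 0.267), where the interneuron median was 0.011. The meningeal gene Ogn (−0.61) lost its call without wild-type array 2 or transgenic array 3 (up to 0.0652). Astrocyte markers had a median of 0.033 (adjusted p = 0.398) and microglial markers of 0.085 (adjusted p = 0.0823). Over the 7 alternatives of the 12 called lists, the lowest adjusted p-values ran from 2.53e-18 to 0.0218 and the estimated correlation always gave the highest.

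Effects in the hippocampus at the 2 ages were then compared. Every gene called at 10 weeks had the same sign at 20 weeks, with 18 called higher at both ages and 141 called lower at both. Of the genes called at 20 weeks 90.62% had the same sign at 10 weeks, against 64.23% of all genes tested. The ages share no array, but both tests use the same spread of each gene, so the called lists are not independent, and with the spread of each age alone 0 genes were called at both. Across all genes the effects correlated with r = 0.559 and rho = 0.451; genes are not independent replicates. For the genes called at 10 weeks, the median size of the change was 0.5 at 10 weeks and 0.52 at 20 weeks.

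Tested directly, limma called 0 genes for a difference between the effects at 20 and 10 weeks, and 949 genes (4.76%) had an unadjusted p below 0.05. The smallest adjusted p was 0.942, and the median 95% confidence interval of a difference reached 0.284 to either side. The genes of smallest p are therefore given as values: Skor1 0.92 (SE 0.191), Kin 0.64, Spag6 0.63, Dmrt2 0.62 and Twist1 0.49 on the positive side, and Foxl1 −0.53, Sct −0.53, Calcb −0.48, Gper1 −0.45 and Acta1 −0.35 on the negative side. Without the 20-week transgenic array 1, limma called 126 genes (77 higher, 49 lower). Of the 34 lists, camera called 6, all of them lost with an estimated correlation (adjusted p = 0.974). Choroid plexus markers (0.32), oligodendrocyte markers (0.15), chaperones (0.11) and ribosomal protein genes (0.066) had positive median differences, and immediate early genes (−0.15) and meningeal markers (−0.15) negative ones. Leaving out that array ended the calls of the choroid plexus (adjusted p = 0.0523), ribosomal (0.105), immediate early (0.313) and meningeal (0.195) lists. Over the 7 alternatives the adjusted p of the 6 lists ran from 0.000528 to 0.976. Age and sex differed together between these sets.

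**Figure D3:**
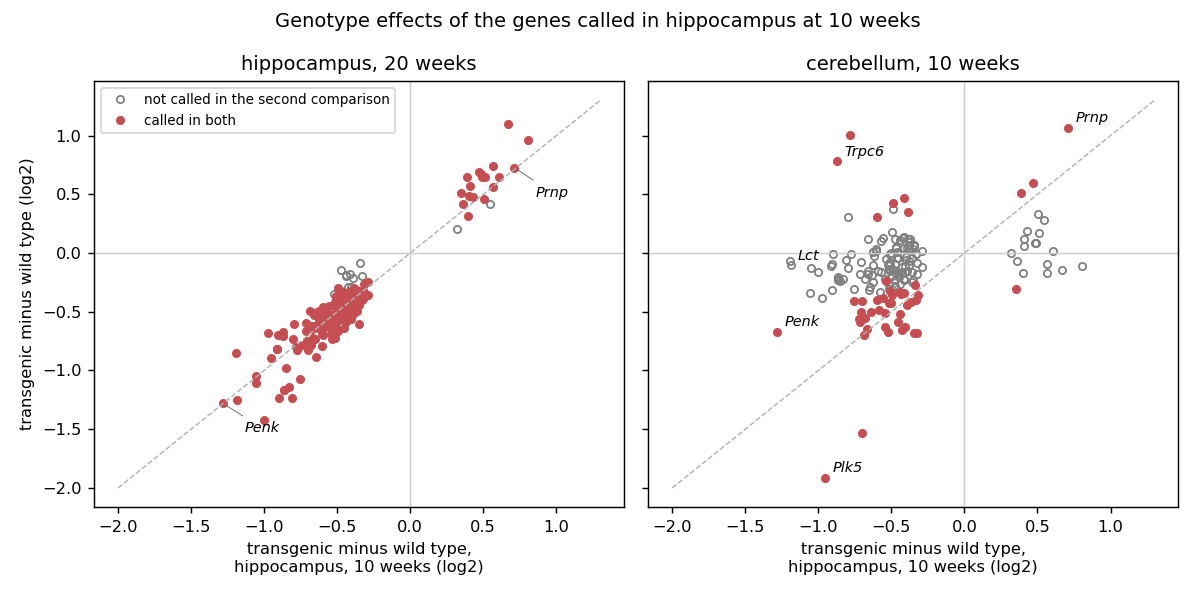
Log2 change (transgenic minus wild type) of the genes called in hippocampus at 10 weeks (horizontal axis) against the change of the same genes in hippocampus at 20 weeks (left, vertical axis) and in cerebellum at 10 weeks (right, vertical axis). Filled points were called in both comparisons, and the dashed line marks equal changes. At 10 weeks 129 of the genes (75.4%) had the same sign in hippocampus and cerebellum, against 57.78% of all genes tested.

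The third comparison concerned the cerebellum at 10 weeks. The falls were larger here. Pappa, a protease of insulin-like growth factor binding proteins, fell by 2.25 (SE 0.149, 4.75-fold, adjusted p = 7.92e-09), from 8.93 (SD 0.383) to 6.68 (SD 0.0902), and Igfbp5, one of those binding proteins, by 2.1 (SE 0.12, 4.28-fold, adjusted p = 1.46e-09), with n = 3 per group. Plk5 (−1.91), the tetraspanin gene Tspan18 (−1.88), Eomes, a transcription factor of unipolar brush cells (−1.76), Stap2 (−1.70), Chil5 (−1.70), the metabotropic glutamate receptor gene Grm4 (−1.545), the p38 kinase gene Mapk12 (−1.53) and the carbonic anhydrase gene Car4 (−1.53) followed. The largest rises were those of the interferon-inducible gene Ifi203, by 1.98 (SE 0.273, 3.94-fold, adjusted p = 9.88e-05), and Slc44a5, by 1.83 (SE 0.1, 3.57-fold, adjusted p = 1.46e-09). Ifi203 went from 6.80 (SD 0.186) to 8.78 (SD 0.733), so its transgenic arrays varied widely. Plppr1 (1.74), the nociceptin receptor gene Oprl1 (1.58), the postsynaptic scaffold gene Lrrc7 (1.48), Muc15 (1.47), the X-linked protocadherin gene Pcdh11x (1.37), the glycine receptor gene Glra2 (1.35), the sodium channel subunit gene Scn3b (1.33) and Necab1 (1.31) rose as well. All of these kept their calls when any 1 array was left out.

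In cerebellum limma called 1230 genes, 514 higher and 716 lower. Of these, 271 changed by at least 1.5-fold, 117 higher and 154 lower. The groups did not overlap in 6991 genes (35.1%, where 10% is the chance for 1 gene), 1222 of them called. The medians of the transgenic arrays (7.58 to 7.63) all lay below those of the wild-type arrays (7.64 to 7.68). Such a shift of whole arrays can part many genes at once. Median centring of the arrays turned the split to 698 higher and 507 lower. The median change over all genes was −0.05. Leaving out wild-type array 1 gave 775 calls, wild-type array 3 gave 789, transgenic array 2 gave 765 and transgenic array 3 gave 736, and the spread of these 6 arrays alone gave 2692. With the replicate number as a block the count was 1232, and 1074 of the calls recurred.

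Immediate early genes fell in cerebellum, 11 of 29 members, while 1 rose and 17 did not pass (14 lower and 1 higher adjusted over the list alone). The largest falls were in the phosphatase genes Dusp5 (−1.27, SE 0.11) and Dusp1 (−1.20, SE 0.109) and in the nuclear receptor genes Nr4a2 (−1.18, SE 0.116) and Nr4a3 (−0.75). Ier5, chosen after its values were seen, rose by 0.43 and lost the call without any array but wild-type array 3 (adjusted p up to 0.186) and with the replicate block (0.0935). The list median was −0.22 (adjusted p = 0.477 with an estimated correlation). Neuropeptide and granin genes fell in 5 of 25 members, with a median of −0.18 (10 over the list alone; adjusted p = 0.361 with an estimated correlation), namely Sst (−0.73), Penk (−0.67), Vgf (−0.56), Chgb (−0.55, SE 0.0787) and Scg2 (−0.45). Vgf was chosen after its values were seen and lost the call without wild-type array 1 or 3 or transgenic array 2 or 3 (up to 0.154), and Sst lost it without wild-type array 3 or transgenic array 2 or 3 (up to 0.0992). REST-controlled genes fell in 6 of 25 and rose in 1, with a median of −0.16 (10 and 1 over the list alone; adjusted p = 0.361 with an estimated correlation), including the neurotrophin gene Bdnf (−0.67) and the neurofilament gene Nefh (−0.42). The 1 that rose, Sez6 (0.26), was chosen after its values were seen and lost its call without any array but wild-type array 3 (up to 0.187) and with the replicate block (0.0723).

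Habenular and thalamic markers fell in 4 of 18 members in cerebellum (6 lower and 1 higher over the list alone; adjusted p = 0.361 with an estimated correlation). These were the nicotinic receptor genes Chrna3 (−0.91, SE 0.111) and Chrnb4 (−0.71, SE 0.0946), Ramp3 (−0.53) and Prkcd (−0.50), and the list median was −0.13. GABAergic interneuron markers had a median of −0.18, and Sst and Gad2 (−0.26), which makes GABA, fell of 19 (4 over the list alone; adjusted p = 0.726 with an estimated correlation). Sst lost its call without wild-type array 3 or transgenic array 2 or 3 and Gad2 without any array but transgenic array 2 (adjusted p up to 0.0992 and 0.206), and Gad2 lost it with the replicate block too (0.0895). Cytosolic ribosomal protein genes were higher, with a median of 0.19 and 22 of 23 members positive (2 rose, 12 over the list alone; adjusted p = 0.361 with an estimated correlation). The 2 were Rps4x (0.38) and Rpl8 (0.43), the latter lost without wild-type array 1 or transgenic array 3 (up to 0.0741). Choroid plexus markers were higher too, with a median of 0.29 and 2 of 17 called (2 over the list alone; adjusted p = 0.726 with an estimated correlation). Otx2 rose by 0.82 and Sostdc1 by 1.31, and the latter lost its call without wild-type array 2 or transgenic array 2 or 3 (up to 0.146). The choroid plexus gene Ttr lay at 10.96 on wild-type array 2 and between 12.35 and 13.40 on the other cerebellum arrays. Cholesterol synthesis genes (median 0.07, 1 higher and 1 lower of 20) and developmental homeobox genes (median −0.14, 1 higher of 29) passed camera, and both calls were lost under quantile normalisation (adjusted p = 0.0735 and 0.103) and with an estimated correlation (0.726 for each). Over 6 alternatives the lowest adjusted p-values of these 9 called lists ran from 3.39e-09 to 0.0209, and the estimated correlation gave the highest for each.

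Lists of cerebellar neurons did not pass camera. Granule neuron markers had 4 members lower and 1 higher of 19 (7 and 2 over the list alone, adjusted p = 0.088), among them the synaptic organiser gene Cbln1 (−0.59, SE 0.119) and Gabrd (−0.35). Of 17 Purkinje neuron markers 0 were called, with a median of −0.10 (adjusted p = 0.121). Glutamate receptor genes changed in both directions, 6 lower and 1 higher of 21 (adjusted p = 0.0566): Grm4, Grm2 (−0.73) and the kainate receptor gene Grik3 (−0.46) fell, and Grm5 rose by 0.61 (SE 0.1). Among potassium channel genes 7 fell and 2 rose of 34 (adjusted p = 0.0589), with Kcnd2 at −0.46 and Kcnk2 at 0.89 (SE 0.0928). Calcium signalling genes fell in 7 of 37 (adjusted p = 0.0612), including the AMPA receptor auxiliary subunit gene Cacng3 (−1.08, SE 0.123), the kinase gene Camkk2 (−0.95) and Nrgn (−0.81), a calmodulin-binding protein gene. In the striatal list 6 fell and 3 rose of 20 (adjusted p = 0.0859), the latter including the phosphodiesterase gene Pde1b (0.62) and Rgs9 (0.53). Astrocyte (median −0.043, adjusted p = 0.85), microglial (−0.037, 0.85) and oligodendrocyte markers (−0.10, 0.353) were not called as lists. Gfap, an astrocyte filament gene, fell by 0.34 and lost its call without wild-type array 1 or transgenic array 1 or 3 (adjusted p up to 0.201).

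The last comparison asked how the effect in cerebellum differed from that in hippocampus at 10 weeks. For 307 genes limma called a difference, 149 positive and 158 negative, and 217 of them differed by at least 1.5-fold. Lrrc7 differed by 1.602 (SE 0.12, adjusted p = 4.93e-07), Scn3b by 1.70, Slc44a5 by 1.61, Plppr1 by 1.56 and the Wnt antagonist gene Sfrp4 by 1.23, all more positive in cerebellum. Stap2 differed by −1.535 (SE 0.107, adjusted p = 2.95e-07), Grm4 by −1.46, Eomes by −1.60, Chil5 by −1.65 and Tspan18 by −1.85. These 10 kept their calls in all 12 fits with 1 array left out. The count itself fell to 202 without transgenic hippocampus array 2, to 195 without transgenic hippocampus array 3 and to 197 without transgenic cerebellum array 3, and the median-centred split was 177 positive and 110 negative.

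Dentate granule neuron markers differed as a list between the tissues, with a median difference of 0.57 and 6 members called positive and 1 negative of 16 (11 and 1 adjusted over the list alone; adjusted p = 0.277 with an estimated correlation). Of the positive ones Dsp and Pdzd2, chosen after their values were seen, lost their calls with the replicate block (adjusted p = 0.0991 and 0.105). Trpc6, which fell in hippocampus and rose by 0.78 in cerebellum, differed by 1.65 (SE 0.154), Lct by 1.09, Rfx3 by 0.64 and Npnt by 0.60. CA neuron markers (0.175; adjusted p = 0.516 with an estimated correlation), choroid plexus markers (0.34; 0.584), cholesterol synthesis genes (0.17; 0.983) and ribosomal protein genes (0.18; 0.487) had positive median differences as well. Over 6 alternatives the adjusted p of these 5 lists ran from 1.7e-15 to 0.983. Neurod6 differed by 1.11, Ptgs2 by 1.13, Nr4a2 by −1.23 and Dusp1 by −0.94. In wild-type cerebellum Neurod6 lay at 5.81, below the lower quartiles of those arrays (6.12 to 6.17), which left little room for a fall. The dentate granule and CA neuron lists fell in hippocampus, so their differences need not mean a response in cerebellum.

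Of the genes called in hippocampus at 10 weeks, 129 (75.4%) had the same sign in cerebellum, against 57.78% of all genes tested. Called in the same direction in both tissues were 3 higher and 37 lower genes, with the replicate number as a block 24 in all, and with the spread of each set alone 61. The sets share no array, but in the main fit both tests use the same spread of each gene. Across genes r was 0.267 and rho 0.263, over genes that are not independent replicates. In all 3 comparisons 46 genes were called, and 39 of these changed in 1 direction throughout. With the replicate block 24 of the 46 were called in all 3, 22 of them in 1 direction; 8 lost the call in cerebellum (adjusted p from 0.0508 to 0.0874), 7 of them among the 39. Of the 39, the 3 higher ones were Prnp, the cold-inducible RNA-binding protein gene Cirbp and the transcription factor gene Nfya, of which the last 2 were chosen after their values were seen; Cirbp lost its call at 10 weeks in hippocampus without wild-type array 3 or transgenic array 2 or 3 (adjusted p up to 0.114). Penk, Plk5, Chgb, Kcnh3, Gabrd and Prkcd were among the 36 lower ones. Plk5 fell further in cerebellum (difference −0.96, adjusted p = 0.0205), a difference lost without wild-type array 2 or transgenic array 2 or 3 of hippocampus, or wild-type array 3 or transgenic array 2 of cerebellum (adjusted p up to 0.0739).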

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

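The patterns weighed here were chosen after the results were seen. The tests of a mislabelled genotype, of a weaker genotype effect in 1 pool, of fewer granule neurons and of slopes against chance were also written after the result was seen, and the others before.

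Transgenic array 1 of the 20-week hippocampus stood apart, with a mean correlation of 0.973 with its group. A swapped genotype label is argued against by Prnp, which lay 0.765 above the highest wild-type array of that age. A narrower signal range is argued against by its distance from its partners, which after forcing 1 distribution was still 1.36 times the largest distance of any other array. A weaker effect in that pool is argued against by a slope of 1.18 on the 10-week effects, against 0.952 and 1.11 for the other arrays. What sets the pool apart (its animals, their dissection or RNA quality) stays open and was not tested.

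Dentate granule neuron markers fell in transgenic hippocampus at both ages, though with an estimated correlation the list passed only at 10 weeks (adjusted p = 0.00634, against 0.166 at 20 weeks). At 10 weeks the highest median among astrocyte, microglial, oligodendrocyte and CA neuron lists was 0.00867, and at 20 weeks the same medians were 0.548 apart, from −0.344 for CA neurons to 0.204 for oligodendrocytes. How far a loss of granule neurons would move these lists is not known, so the medians do not decide whether granule neurons were fewer. Signal range is argued against by a median of −0.539 with the arrays of a tissue forced to 1 distribution. Of the called members at most 16.7% lay on 1 chromosome. The list was fixed in advance and its called members lie on 10 chromosomes, so this share could hardly have been high. It does not decide whether a strain difference lowered the markers. Fewer granule neurons, lower expression within them, the dissection and a strain difference all stay open.

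Counts over re-split arrays were weighed only for whether chance can be excluded. In the 10-week hippocampus and in the cerebellum 1 of 10 splits, the real one, called as many genes (highest other 12 and 1), and 10 splits are too few to exclude chance. In the 20-week hippocampus 2 of 10 did, and a false grouping called 1546 genes against 1119 for the real one, so the counts decide nothing there. The genes called at 10 weeks were also followed on the 20-week arrays. All of these had the same sign at 20 weeks, with slopes on the 10-week effects of 1.18, 0.952 and 1.11 for the 3 transgenic arrays. The slopes share 1 wild-type mean and run over genes that can move together, so they are not independent checks. How far chance alone would move them is not known, and they do not exclude chance. For the difference between ages the real count was 0, so that all 100 of 100 splits called as many by construction (highest other 5635), which decides nothing. For the difference between tissues 6 of 100 called as many as the real 307, the real one included (highest other 666). All 6 kept the true genotypes of the cerebellum arrays and so carry that effect, and the highest count among splits that did not was 138, so the 6 are no measure of chance.

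More genes changed by at least 1.5-fold in cerebellum than in 10-week hippocampus, by a ratio of 4.67, and of 3.70 with all arrays forced to 1 distribution. At most 9.59% of those genes lay on 1 chromosome. Their median absolute correlation with the choroid plexus gene Ttr was 0.472, against 0.452 for all genes.

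The genotype effect differed between cerebellum and 10-week hippocampus for 307 genes. The differences were 1.602 for Lrrc7, 1.696 for Scn3b, 1.615 for Slc44a5, 1.558 for Plppr1 and 1.225 for Sfrp4. They were −1.535 for Stap2, −1.455 for Grm4, −1.604 for Eomes, −1.653 for Chil5 and −1.846 for Tspan18. In opposite directions in both tissues, with a called difference, were 7 genes. With the replicate block 2 genes were called in opposite directions, and of the 7 Cdc40, chosen after its values were seen, lost its cerebellum call (adjusted p = 0.0731).

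Median differences between cerebellum and hippocampus were 0.175 for CA neuron markers, 0.566 for dentate granule neuron markers, 0.342 for choroid plexus markers, 0.167 for cholesterol synthesis genes and 0.181 for ribosomal protein genes. Between 20 and 10 weeks in hippocampus they were −0.146 for immediate early genes, 0.153 for oligodendrocyte markers, 0.324 for choroid plexus markers, −0.146 for meningeal markers, 0.107 for chaperones and 0.0655 for ribosomal protein genes. None of these lists held with an estimated correlation (adjusted p from 0.277 to 0.983).

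Probe sets with no gene or several genes listed numbered 13767, and 8, 245 and 256 of them were called in 10-week hippocampus, 20-week hippocampus and cerebellum.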

How the results depend on the processing

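The tests and most other ways of running them were fixed before the data were examined. Quantile normalisation within each set, rescaled list tests and fits without the 20-week transgenic array 1 were chosen after the data were seen. A count was taken as the same where it lay within a factor of 1.5 of the main count. Neither the direction of the calls nor which genes were called entered that rule. By it, 95 of 158 alternatives to 12 results were the same and 63 moved. Unless stated, the cause was not tested.

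In 10-week hippocampus the counts of called genes were 495 with quantile normalisation across the tissue, 396 within the set, 8449 with array weights, 92 at an adjusted p of 0.01, 258 at 0.1, 58 at 1.5-fold, and 82 to 117 with 1 array left out. In 20-week hippocampus (main 1119) they were 0 with only the arrays compared, 1689 and 1991 with the same normalisations, 8689 with weights, 3958 with quantile normalisation and without transgenic array 1, 264 and 2213 at the other thresholds, 131 at 1.5-fold, and 259 to 6445 with 1 array left out. In cerebellum (main 1230) they were 2692 with only the arrays compared, 1867 with quantile normalisation within the set, 5137 with weights, 649 at 0.01, 271 at 1.5-fold, and 736 to 1106 with 1 array left out. Thresholds lower or raise a count by construction. Array weights reached 9.37 and 8.92 in 10-week hippocampus, where 1 array per genotype carried most of the fit, and ran from 0.0803 to 2.24 in 20-week hippocampus and from 0.532 to 1.88 in cerebellum.

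The difference between ages (main 0) gave 3932 with weights, 55 with quantile normalisation and without transgenic array 1, and 0 to 126 with 1 array left out. The difference between tissues (main 307) gave 585 with only the arrays compared, 628 and 601 with quantile normalisation, 3635 with weights, 155 and 464 at 0.01 and 0.1, and 195 to 263 with 1 array left out. Genes called in 1 direction at both ages (main 159) numbered 0 with only the arrays compared, 397 with quantile normalisation and 48 at 1.5-fold. For 10-week hippocampus and cerebellum (main 40) the numbers were 61, 142 and 6, and 24 with the replicate block.

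Called lists in 10-week hippocampus went from 16 to 2 with an estimated correlation and 5 with fry. In 20-week hippocampus they went from 12 to 0 and 7, and to 10 without transgenic array 1, where the GABAergic interneuron median was 0.011. In cerebellum they went from 9 to 0 with an estimated correlation and to 14 with median centring. Fry called 11 lists there, of which 6 were among the 9. For the difference between ages they went from 6 to 0 and 0, to 3 with quantile normalisation and to 5 without that array, and for tissues from 5 to 0 and 1.

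Sign changes were followed for Htt and for the named genes that were called; 0 of the latter changed sign, and Htt did, without a call. With 1 array left out it ran from −0.03349 to 0.02918 in 10-week hippocampus (negative without wild-type array 1 or, at −0.001162, transgenic array 3). In cerebellum it ran from −0.002993 to 0.09011 (negative without wild-type array 2 or, at −0.0003786, transgenic array 2). Of the genes named by the rule and called, 28 of 47, 46 of 73 and 60 of 75 kept their calls in every fit with 1 array left out (10-week hippocampus, 20-week hippocampus, cerebellum). With only the arrays compared 39, 0 and 74 did.

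With the replicate number as a block the counts were 130, 1221, 1232, 0 and 267, with 117, 920, 1074, 0 and 235 of these called in the main fit. Of the same genes, 10 of 47, 7 of 73, 3 of 75 and, for tissues, 5 of 35 lost their calls. In cerebellum these were Chn2, Gad2 and Ppargc1b (adjusted p = 0.0718, 0.0895 and 0.0579), and for tissues Chn2, Otx2, Stat2, Plk2 and Fkbp5 (up to 0.108). Genes chosen after their values were seen are not in this tally, and some of them lost their calls as well. The circadian clock list was called in cerebellum (0.0347) and the thalamic and habenular list for tissues (0.0273). In 20-week hippocampus and cerebellum each array correlated best with its own number, and in 10-week hippocampus not, which is a hint from the values and not from the design. The tests of age and of tissue and the other ways of running them were not run. With 3 pools per group, the number of arrays limits the precision.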

Other observations

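The patterns in this part were noticed after the results were seen. The protocadherin beta genes, which encode neuronal adhesion proteins and lie together on chromosome 18, rose together in transgenic cerebellum. There 19 of 22 were called and all 19 were higher, against 1.36 expected (adjusted p = 7.22e-18, Fisher's exact test, one-sided), with a median change of 0.436. In hippocampus at 20 weeks 13 of 22 were called higher (median 0.394, adjusted p = 9.8e-09 by the same test). At 10 weeks 0 were called, with a median of 0.134 and 21 of 22 positive. With only the 20-week arrays in the fit, limma called 0 genes of any kind at that age. Fisher's exact test counts the members as independent, but they correlated with each other (median 0.371, against 0.112 for random genes). Its p-values therefore overstate the evidence and do not measure the spread between pools. Tested directly, 0 of 22 differed between the ages in hippocampus, and 3 of 22 differed between cerebellum and 10-week hippocampus, Pcdhb3, Pcdhb5 and Pcdhb9, the last 2 not with the replicate block (adjusted p = 0.0823 and 0.0623). Pcdhb3 rose by 0.879 (SE 0.0769), Pcdhb2 by 0.869 and Pcdhb9 by 0.817 in cerebellum, and Pcdhb22 by 0.566 in 20-week hippocampus, all chosen after their values were seen. Median centring gave 0, 16 and 19 calls and quantile normalisation 0, 13 and 20, in 10-week hippocampus, 20-week hippocampus and cerebellum.

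Over 618 families named by a shared symbol stem, 4 were over-represented among called genes in 20-week hippocampus, 2 in cerebellum and 0 in 10-week hippocampus. The 20-week families rest on the 1119 calls of the main fit. With only the arrays of that age limma called 0 genes, and a false grouping of them in the main fit called 1546. Besides the protocadherins these were Camk (6 of 10, 2 higher and 4 lower), Stx (6 of 14) and Scn (5 of 11) in hippocampus. In cerebellum the metabotropic glutamate receptors stood out, with 5 of 7 called (adjusted p = 0.00518): Grm2, Grm4, Grm7 and Grm8 fell and Grm5 rose. Grm7 lost its cerebellum call with the replicate block (adjusted p = 0.0533), as did 1 protocadherin beta gene, Pcdhb13 (0.0516). Pcdhb5 and Pcdhb8 lost their calls in 20-week hippocampus with that block (adjusted p = 0.051 and 0.0592).

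For the protocadherins, signal range is argued against by 93.8% of the calls (30 of 32) staying with the arrays of a tissue forced to 1 distribution. A strain difference that changes most genes of the region is argued against by the neighbouring genes within 5 Mb. Of these, 8.42% were called in cerebellum, against 6.17% of all genes. A strain difference within the cluster itself would not have to move its neighbours and stays open. Members correlated with each other at a median of 0.371 beyond the group means, against 0.112 for random genes, so probes shared between similar copies stay open.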
